A study of Aspergillus luchuensis with 6 samples.

How the data were processed

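CAGE (cap analysis of gene expression) captures the capped 5′ ends of transcripts, so each sequenced tag marks a transcription start site (TSS) at the level of a single base. The libraries came from Aspergillus luchuensis mut. kawachii, the white koji mould used in brewing, per the labels. RNA was extracted from rice koji, steamed rice overgrown by the mould, that had been frozen in liquid nitrogen, and the libraries were sequenced on an Illumina NextSeq 500, per the labels and the series design. There were 6 libraries, 3 from a control strain and 3 from a strain in which the sirtuin D gene (sirD) was disrupted. Sirtuins are NAD-dependent protein deacylases, many of which act on histones. Groups and replicate numbers were taken from the labels. The labels do not say whether replicates of a strain came from separate cultures, so every p-value measures the spread between these libraries, which may be technical. Each group is also a single strain, so a difference between groups is a difference between these strains.

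The deposited values were whole-number counts of tags per position and strand, with 6 columns that were matched to the 6 samples through their descriptions. FastQC, BWA and bedtools are named in the submitters' processing notes, without versions. The mapping settings, the genome build and the treatment of reads with several matches are not given in the sources used here. Sequence names in the deposited table were used as coordinates. Positions there count from 0, and 1 was added to each. The lowest minus-strand position was 31, which is what 5′ ends of reads of at least that length give, so minus-strand positions were read as 5′ ends.

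The table held 1048575 rows, which equals the row limit of a spreadsheet less its header line. Its rows were in text order and stopped inside the second scaffold. They covered 557 sequences, namely scaffold 1 (DF126447.1, positions 1311 to 2077004), part of scaffold 2 (DF126448.1, positions 1009 to 2007002), a sequence of 31 kb (AP012272.1) and 554 short contigs, of which 289 had a tag. In text order, longer positions that begin with a lower digit come before the last row. Positions well beyond 2007002 would therefore have been listed, and scaffold 2 was taken to end near 2007002. Scaffold 2 had no rows at 47455 to 100011 and at 474756 to 1000002. Stretches without rows shorter than 40000 bp were not looked for on scaffold 2. By the text order, positions with fewer digits that sort after the last row are also missing, in a shorter stretch of its low end. The rows spanned 3.50 Mb of scaffold with that stretch counted in, and the rest of the genome was not analysed here. Totals over the table are therefore not the full depth of the libraries. Of all rows, 469501 (44.8%) had 0 tags in all 6 libraries.

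No genome sequence or gene annotation in these coordinates was used. The table of gene names at hand belongs to another assembly, AkawachiiIFO4308_assembly01, and the deposited rows hold no gene identifiers to match to it. Comparisons planned for genes, including 24 gene lists fixed before the data were examined, tag shares by gene annotation and the bases at start sites, were not analysed here. The disrupted gene could not be located, so its level in each library, which would check the labels, is not reported here. The planned analysis of TSS clusters took the place of genes.

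Positions with 2 or more tags over the 6 libraries were joined into a cluster when 20 bp or less apart on 1 strand, which gave 36260 clusters. Clusters held 98.5% to 98.8% of the tags of each library. Clusters passing edgeR's filterByExpr (4083) were scaled by TMM and compared between strains with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) without covariates. P-values were adjusted by the Benjamini-Hochberg method and a cluster was called changed below 0.05. Levels are in CPM, the tags of a cluster scaled to a common total of the tested clusters with TMM factors, as mean ± SD of 3 libraries, and log2 differences are disruptant minus control with their standard error (SE). Named clusters are, by a rule set before the data were examined, the 10 higher and 10 lower with the smallest p and the 5 with the smallest p for start-site usage. Any other cluster named was chosen after its values were seen.

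Start-site usage within clusters was tested with edgeR's diffSpliceDGE, with a Simes p per cluster and Benjamini-Hochberg adjustment. Tested positions had 10 or more pooled tags and passed filterByExpr. Position shares and mean starts used all positions with 10 or more pooled tags in these clusters, tested or not. This replaced the planned test of cluster usage within genes. Neighbouring clusters called in the same direction were counted on the 2 scaffolds and set against 10000 shuffles of the calls over cluster order, so that the smallest p was 0.0001. A leading cluster is the most abundant of its strand within 2 kb. Clusters within 100 kb of a scaffold end were compared with the others by camera with a preset correlation of 0.01 and by two-sided Fisher's exact tests. Widths are the distance between the 0.1 and 0.9 quantiles of the tags of a cluster, for clusters with 50 or more tags in every library, after thinning each library to 3148498 tags. Widths and tag shares were compared by two-sided exact permutation tests, whose smallest p with 3 libraries against 3 is 0.1. Intervals on ratios of tags are 95% exact (Clopper-Pearson) and cover counting error only, not the spread between libraries. Whether each tag is a separate molecule is not given in the sources used here, so they may be too narrow.

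The tests were tried on simulated data first. With 3885 clusters in all, the cluster test recovered 16.9% of 65 clusters changed 1.5-fold, 60% of 65 changed 2-fold and 100% of 66 changed 4-fold, and 7.2% of its calls were false. The usage test recovered 53% of 200 clusters in which 50% of the leading position's tags were moved, and 5.36% of its calls were false. Camera gave p below 0.05 for 0% of 200 random sets, and the neighbour test for 4% of 50 random sets of calls. These sets and calls were drawn at random over clusters, so the rates do not cover clusters that change together with their neighbours. Replicate libraries of a strain differed by more than sampling noise in every pair (chi-square per degree of freedom 6.80 to 15.0), so each was counted as its own library. Alternatives were other scalings, filters, cluster definitions, DESeq2 (1.42.0), a replicate block and leaving out each library in turn. Tables and plots used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.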

Results

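Transcription start sites were profiled by CAGE in rice koji of the white koji mould, Aspergillus luchuensis mut. kawachii, from a control strain (n = 3) and a sirD disruptant strain (n = 3). The table listed 3148498 to 3275687 tags per control library and 3336690 to 3580777 per disruptant library. A library had tags at 188530 to 218877 positions. Short contigs took 48.3% ± 1.68 of the control tags (SD, n = 3), scaffold 1 took 25.9% ± 1.06, scaffold 2 took 19.8% ± 0.713 and the 31-kb sequence took 6.07% ± 0.292. In the disruptant these shares were 48.6% ± 2.86, 25.9% ± 1.61, 20.1% ± 1.11 and 5.39% ± 0.649 (SD, n = 3). No difference between the 4 pairs of shares could pass 0.05 with 3 libraries each (two-sided exact permutation tests, p = 0.9, 1.0, 0.6 and 0.3 in the order given, adjusted p of 1.0 each, smallest possible 0.1).

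The first comparison asked which start sites are used more or less when sirD is disrupted. Of 4083 TSS clusters tested, 426 were higher and 573 were lower in the disruptant. The median log2 difference was −1.21 for the lower and 0.94 for the higher clusters. At least 2-fold changes were seen in 367 lower and 196 higher clusters, and at least 4-fold changes in 71 lower and 23 higher. Changed clusters lay on both scaffolds, with 261 higher and 334 lower of 2499 on scaffold 1 and 154 higher and 223 lower of 1433 on scaffold 2. On the short contigs 10 were higher and 15 lower of 98, and on the 31-kb sequence 1 was higher and 1 lower of 53. Among all tested clusters, 39.7% had no overlap between the 3 libraries of each strain, where chance gives 10%. The first principal component of the log levels held 58.6% of the variance and placed the strains on opposite sides. Correlations of log levels across clusters were 0.972 to 0.981 between libraries of 1 strain and 0.934 to 0.952 between strains, with clusters not being independent replicates.

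**Figure D1:**
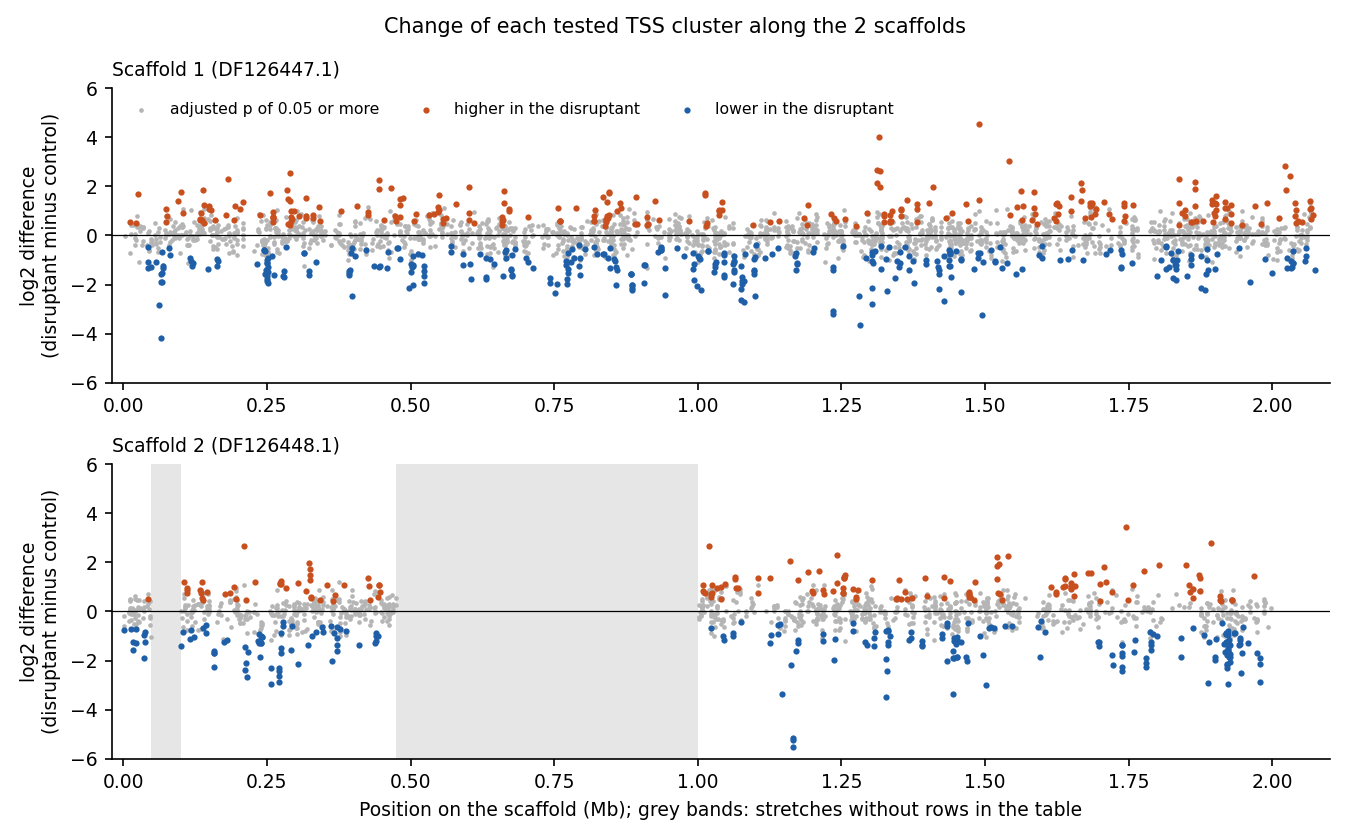
Log2 difference in tag level (disruptant minus control) of each tested TSS cluster against its position on scaffold 1 and scaffold 2 in Mb. Orange points are the clusters higher and blue points the clusters lower in the disruptant (edgeR, adjusted p below 0.05), grey points are the other tested clusters, and grey bands are the stretches of scaffold 2 without rows; changed clusters are spread over both scaffolds, and the lowest points, at −5.52 to −5.14, lie side by side on scaffold 2.

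The start site with the smallest p was nearly silent in the disruptant. This cluster, on the plus strand of scaffold 2 at 1165210 to 1165334, fell from 342 ± 162 CPM in the control to 9.17 ± 0.587 in the disruptant (SD, n = 3), a 37.1-fold drop (log2 −5.21, SE 0.29, adjusted p = 3.25e-10). Tags numbered 672, 970 and 1535 in the control libraries and 33, 30 and 30 in the disruptant libraries. On the same strand, the small clusters at 1165410 to 1165421 and at 1166420 to 1166539 had 77 and 142 tags over the control libraries and 2 and 3 over the disruptant libraries. Those counts are 2.42% (95% interval 0.288% to 9.03%) and 1.97% (0.401% to 5.86%) of the control after scaling. The next cluster upstream on that strand, at 1162656 to 1162726, fell 4.49-fold (log2 −2.17, SE 0.19, adjusted p = 2.44e-07). Downstream, the cluster at 1167824 to 1167980 was at 237 ± 14.8 in the control and 187 ± 7.17 in the disruptant and did not pass the test (adjusted p = 0.072). On the minus strand, the cluster at 1164459 to 1164637 had 906 tags over the control and 828 over the disruptant libraries (log2 −0.24, adjusted p = 0.425).

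The other 8 lower clusters with the smallest p fell 3.69-fold to 5.99-fold. On scaffold 1, the minus-strand cluster at 1281354 to 1281502 fell 5.58-fold, from 689 ± 113 to 124 ± 23.8 CPM (log2 −2.48, SE 0.17, adjusted p = 8.74e-09). The plus-strand cluster at 398857 to 398973 fell from 60.2 ± 4.15 to 10.9 ± 3.18 and the minus-strand cluster at 886268 to 886401 from 179 ± 42.0 to 44.6 ± 6.60. On scaffold 2, the plus-strand cluster at 270327 to 270573 fell 4.96-fold, from 785 ± 165 to 158 ± 45.9 (log2 −2.31, SE 0.20, adjusted p = 1.58e-07). The plus-strand cluster at 303318 to 303402 fell from 84.5 ± 7.85 to 19.1 ± 1.84. Near the high end of scaffold 2, the minus-strand clusters at 1920141 to 1920474 and at 1979262 to 1979621 fell from 297 ± 65.8 to 66.8 ± 8.34 and from 516 ± 55.9 to 140 ± 16.5. A plus-strand cluster at 1 to 35 of the short contig BACL01001044.1 fell from 45.1 ± 10.6 to 7.49 ± 1.12. Its peak was at position 1, the first base of the contig, and whether transcripts start there was not tested. The adjusted p of these 8 clusters ran from 8.74e-09 to 3.75e-07, and their 3 libraries did not overlap between strains.

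The clusters that rose with the smallest p did so 2.38-fold to 6.41-fold. The minus-strand cluster of scaffold 2 at 209896 to 210160 rose most, from 6.92 ± 2.99 to 44.9 ± 10.6 CPM (log2 2.68, SE 0.27, adjusted p = 9.06e-07), followed by the plus-strand cluster of scaffold 1 at 1312182 to 1312246, from 2.76 ± 0.507 to 17.7 ± 2.02 (log2 2.67, SE 0.30, adjusted p = 3.23e-06). Of the more abundant ones, the minus-strand cluster of scaffold 2 at 274034 to 274342 rose 2.38-fold, from 591 ± 6.395 to 1406 ± 42.6, and that of the short contig BACL01000914.1 at 956 to 1234 rose 2.83-fold, from 359 ± 60.7 to 1017 ± 162. Scaffold 1 held the minus-strand clusters at 1669127 to 1669212 (27.1 ± 6.89 to 98.6 ± 9.31), 1685352 to 1685784 (146 ± 15.2 to 366 ± 24.3) and 1707353 to 1707859 (144 ± 20.3 to 369 ± 28.9). It also held the plus-strand clusters at 486045 to 486159 (29.6 ± 1.88 to 86.0 ± 5.67) and 1902646 to 1902949 (32.9 ± 6.58 to 102 ± 8.36). The minus-strand cluster of scaffold 2 at 325517 to 325643 rose from 45.03 ± 4.85 to 125 ± 23.8. The highest adjusted p among these 10 was 4.70e-06, and each was higher in all 3 disruptant libraries than in any control library.

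**Figure D2:**
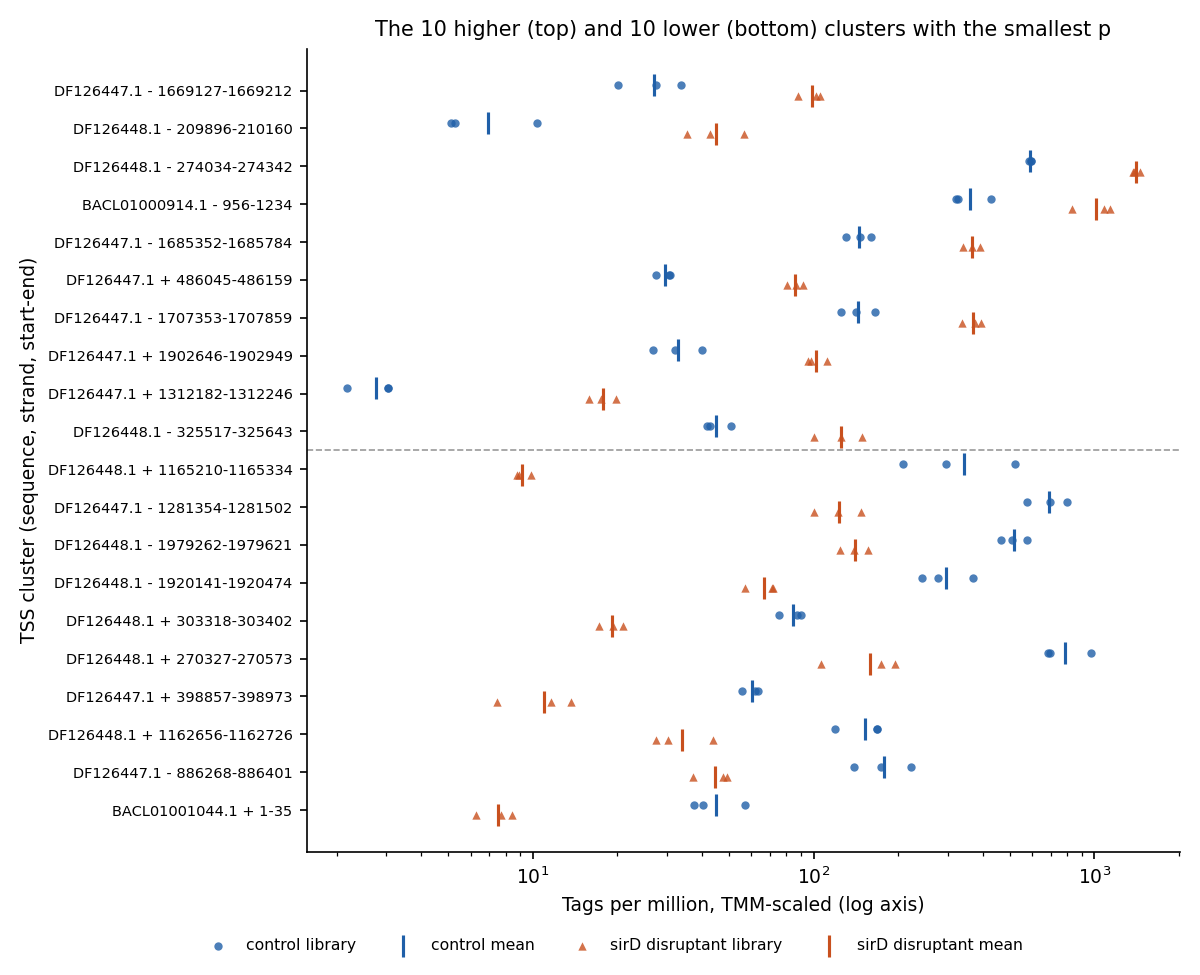
Levels in CPM after TMM scaling (log axis) in each library for the 10 higher (above the dashed line) and 10 lower clusters with the smallest p, named by sequence, strand, start and end. Blue circles are the 3 control libraries, orange triangles the 3 disruptant libraries and vertical ticks the means; the strains do not overlap in any of these clusters, and the widest gap is that of the cluster at 1165210 on scaffold 2, 342 against 9.17.

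Among the most abundant start sites of the scaffolds, chosen by level, some changed and others did not pass the test. The minus-strand cluster at 266467 to 267383 of scaffold 2 was at 16789 ± 2053 CPM in the control and 20076 ± 1124 in the disruptant (adjusted p = 0.153), and the plus-strand cluster at 304446 to 305069 at 14209 ± 1886 and 14485 ± 665 (adjusted p = 0.909). The minus-strand cluster at 461909 to 462111 of scaffold 2 was at 6116 ± 351 and 5365 ± 135 (adjusted p = 0.290). The minus-strand cluster at 246095 to 246417 of scaffold 1 fell from 12652 ± 1058 to 8135 ± 517 (log2 −0.64, SE 0.13, adjusted p = 0.000853). On scaffold 2, the minus-strand cluster at 157788 to 158313 fell from 5074 ± 1093 to 1553 ± 254 (log2 −1.71, SE 0.16, adjusted p = 4.95e-07), and the plus-strand cluster at 1909344 to 1909643 rose from 7141 ± 1161 to 9920 ± 378 (log2 0.47, SE 0.14, adjusted p = 0.0143). On the short contigs, 6 contigs held 95% of the tags. Their most abundant cluster, on BACL01001099.1 at 64 to 698, was at 182443 ± 22702 in the control and 183407 ± 32608 in the disruptant (adjusted p = 0.976).

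The second comparison asked whether changed start sites lie side by side, as genes of 1 pathway often do in this genus. Changed clusters were grouped along the scaffolds. In 30 places 4 or more neighbouring tested clusters changed in the same direction, 23 lower and 7 higher, with 151 clusters in all, where shuffled calls gave 1.73 such runs on average and at most 8 in 1000 shuffles. Of the 30 runs, 17 held clusters on both strands. The shuffles treat clusters of 1 transcript as separate, and runs were not counted among leading clusters, so a run need not be a group of genes. The run with most clusters lay on scaffold 2 at 1921778 to 1924339, where 13 clusters fell with a median log2 difference of −1.56, next to 8 that fell at 1919037 to 1920813 (median −1.07). The longest run, of 12 clusters over 15.6 kb of scaffold 1 (median −1.60), fell into groups at 1062089 to 1063430 and 1075103 to 1077652, with no tested cluster between. Other lower runs lay on scaffold 1 at 250312 to 252140 (8 clusters, median −1.39) and at 65883 to 68159 (6 clusters, median −1.73).

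The 7 higher runs held 4 or 5 clusters each. They included scaffold 1 at 1684274 to 1685784 (5 clusters, median 1.25), scaffold 2 at 323984 to 325643 (4 clusters, median 1.59) and scaffold 2 at 273297 to 274342 (4 clusters, median 1.15). In all, 352 of 3928 pairs of adjacent clusters were called in the same direction, against 123 ± 9.89 (SD over shuffles), a ratio of 2.87 (permutation p = 0.0001, the smallest the shuffles can give). Clusters close together on 1 strand can belong to 1 transcript, and the ratio was 1.51 (89 pairs, permutation p = 0.0001) among 1357 leading clusters, of which 166 were higher and 231 lower. It was 1.20 (42 pairs, permutation p = 0.102) for leading clusters 2 kb or more apart, where the excess no longer passed the test.

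**Figure D3:**
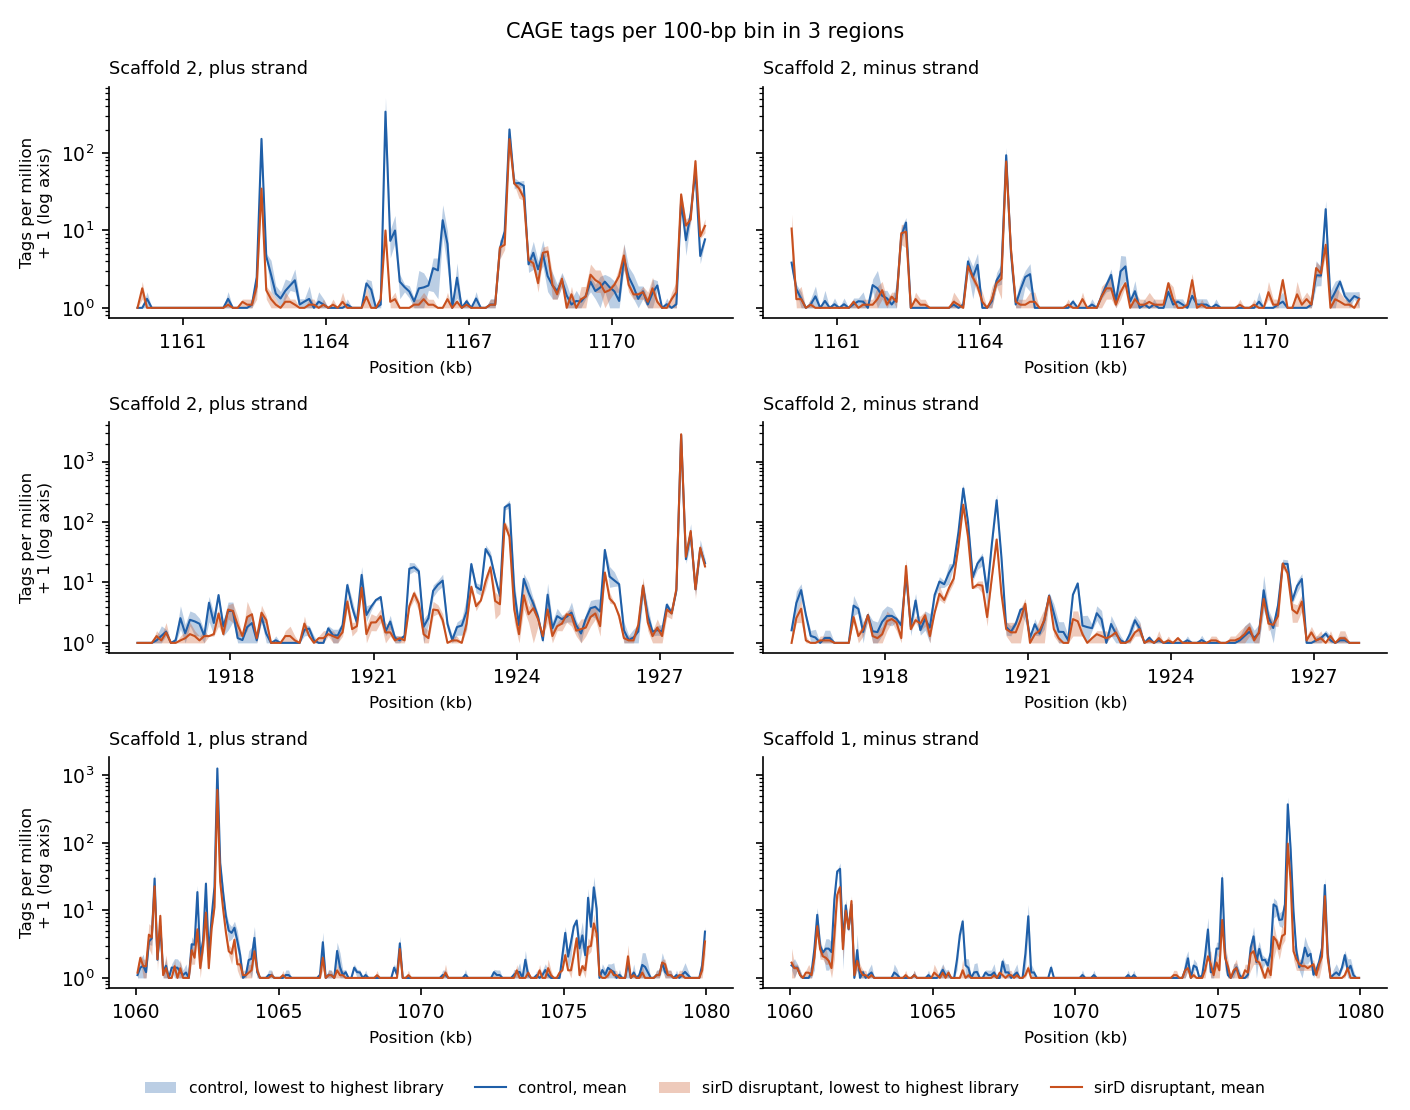
CPM plus 1 (log axis) per 100-bp bin against position in kb, on the plus strand (left) and minus strand (right), in the region of the nearly silent start site on scaffold 2 (top), the runs of lower clusters on scaffold 2 (middle) and the 15.6-kb run on scaffold 1 (bottom). Lines are the means of the 3 control (blue) and 3 disruptant (orange) libraries and bands run from the lowest to the highest library; the control peak at 1165210 to 1165334 is nearly absent in the disruptant, and most peaks of the lower regions are reduced but still present.

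The third comparison asked whether start sites near scaffold ends respond differently, since sirtuins are known to silence genes near chromosome ends in yeast. Lower clusters were more frequent within 100 kb of the scaffold ends, but the difference was lost at other distances, without 1 of the 4 ends and when only leading clusters were counted. Of 380 end clusters, 84 were lower and 32 higher, against 473 lower and 383 higher of 3552 elsewhere (odds ratio for lower 1.85, Fisher's exact p = 9.18e-06; for higher 0.761, p = 0.187). The median log2 difference was −0.13 near the ends and 0.01 elsewhere (camera with the preset correlation, p = 0.0209). With an estimated correlation, the camera p = 0.114. The high end of scaffold 2 held 43 lower and 6 higher of 121 clusters (median −0.38), and it contains the run of 13 lower clusters. Without that end the odds ratio for lower was 1.22 (Fisher's exact p = 0.258) and the camera p = 0.402. The odds ratio was 1.17 within 50 kb (Fisher's exact p = 0.452) and 1.16 within 200 kb (p = 0.191). With all 4 ends and leading clusters alone it was also 1.22 (Fisher's exact p = 0.394). The other 3 ends held 16 lower and 8 higher (scaffold 1, low end), 14 lower and 17 higher (scaffold 1, high end) and 11 lower and 1 higher (scaffold 2, low end, where the table had no rows from 47455 to 100011). By the text order of the rows, a shorter stretch of that low end is missing as well. Scaffold ends were taken as the lowest start and the highest end of any cluster, tested or not. Whether they are chromosome ends is not given in the sources used here.

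The fourth comparison asked whether the position of initiation within a cluster moved. Usage changed in 23 of 1286 clusters with several tested positions (edgeR diffSpliceDGE, adjusted p below 0.05). By sign alone, the mean start moved downstream in 11 and upstream in 12. In 17 of the 23 the mean start did not overlap between the libraries of each strain, and in the others it did. The median size of the move was 14.3 bp. Each adjusted p given below beside a position is that of its cluster, not of the position. The positions named are those with the largest gain or loss of share, picked after the values were seen. For the scaffold clusters only the gain or only the loss is given. The smallest p was found on the minus strand of the short contig BACL01001245.1, in the cluster at 80 to 264, where position 144 took 1.87% ± 1.66 of the tags at the tested positions in the control and 30.2% ± 8.65 in the disruptant (SD, n = 3, adjusted p = 3.31e-09). Its position 190 went from 37.8% ± 32.1 to 0.551% ± 0.213, with a wide spread between control libraries. On scaffold 2, position 1696527 of the minus-strand cluster at 1696340 to 1696988 went from 2.67% ± 0.976 to 0.676% ± 0.0773 (adjusted p = 3.19e-06). Position 365123 of the plus-strand cluster at 364705 to 365360 went from 1.88% ± 0.247 to 0.873% ± 0.190 (adjusted p = 5.13e-05).

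On scaffold 1, position 326611 of the plus-strand cluster at 326264 to 326699 went from 11.5% ± 1.52 to 2.07% ± 1.73 (adjusted p = 8.94e-05), and position 398129 of the minus-strand cluster at 398028 to 398786 from 0.874% ± 0.186 to 2.99% ± 0.497 (adjusted p = 0.000135). The mean start shifted downstream by 34.3 bp in the contig cluster and by 28.5 bp in the cluster at 398028, and upstream in those at 1696340, 364705 and 326264 (downstream shifts of −20.3, −14.3 and −30.2 bp). Clusters with changed usage were also more often changed in level (14 changed and 9 not, against 414 changed and 849 not among the others, odds ratio 3.19, Fisher's exact p = 0.00674). This comparison did not account for tag level, on which both calls can depend, so a link between the changes was not tested. The count of clusters with changed usage was 10 to 15 when any 1 library was left out, and 2 with positions joined within 5 bp. Library medians of cluster width were 72.7 ± 2.89 bp in the control and 73.3 ± 0.577 bp in the disruptant over 1377 clusters (SD, n = 3, two-sided exact permutation test, p = 1.0, smallest possible 0.1).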

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

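Tags outside the comparisons were counted in every library. Positions with a single tag over the 6 libraries held 278683 tags, which entered no cluster, and their share was 1.37% ± 0.192 in the control and 1.40% ± 0.147 in the disruptant (SD, n = 3, two-sided exact permutation test, p = 0.8, smallest possible 0.1). A further 257215 tags lay in 32177 clusters below the count filter, with 1.28% ± 0.154 of the control and 1.28% ± 0.0843 of the disruptant tags (SD, n = 3, exact permutation p = 1.0). Neither share differed beyond the spread between libraries.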

How the results depend on the processing

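Alternatives on the 2 scaffolds alone, total-count scaling, leading clusters, opposite strands and the left-out scaffold end, and those for usage and tag shares, were chosen after seeing the data. The 999 changed clusters (426 higher, 573 lower) stayed within 1.5 times under every other scaling, filter, cluster definition and tool tried, from 820 to 939 with 1 library left out (347 to 416 higher, 461 to 536 lower) to 1397 with positions joined within 5 bp. A 2-fold minimum left 563 (196 higher, 367 lower) and an adjusted p below 0.01 left 616 (245 and 371). The 20 clusters named by level kept their direction and call in all 338 combinations run, with adjusted p up to 0.00201. The median log2 difference of all clusters moved by less than 0.1 under every scaling.

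Deviations correlated at 0.0937, 0.0590 and 0.0418 between same-numbered libraries and −0.0962 to 0.0458 (disruptant 3 with control 2) between others. Pairing by replicate number stays open. With a replicate block 1050 clusters changed (458 higher, 592 lower) and 26 changed in usage; 972 of the 999 calls stayed, and neighbour and scaffold-end tests on all clusters kept their side.

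The 23 clusters with changed start-site usage became 10 to 15 with 1 library left out, 9 with no filter, 7 with clusters built from positions of 10 or more pooled tags, 2 with positions joined within 5 bp and 11 at an adjusted p below 0.01. The cause was not tested, apart from the fewer samples and the stricter threshold. The neighbour ratio of 2.87 was lost in 1 case, at 1.20 for leading clusters 2 kb or more apart, and was 2.96 to 3.47 with 1 library left out and 6.48 with no filter.

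The difference near scaffold ends (log2 −0.15) did not pass the test with no filter (−0.0023, p = 0.499), within 50 kb (−0.026, p = 0.377), with an estimated correlation (−0.15, p = 0.114) or without the high end of scaffold 2 (−0.045, p = 0.402), and turned to 0.026 within 200 kb (p = 0.908); it was −0.20 to −0.10 with 1 library left out. The odds ratio of a call (1.38) did not pass with no filter (1.24), within 50 kb (1.02), within 200 kb (1.16), without that end (1.10), for leading clusters (1.14, and 1.11 without that end), without control library 1 (1.19, the lowest with 1 library left out, where the highest was 1.47) or without disruptant library 2 (1.24). The odds ratio of a lower call (1.85, and 1.62 to 2.02 with 1 library left out) did not pass within 50 kb (1.17), within 200 kb (1.16), without that end (1.22) or for leading clusters (1.22, and 0.995 without that end). Dropping that end or counting leading clusters removes the difference.

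Tag shares and widths could pass no test (smallest p 0.1), and their signs changed between settings except for the 31-kb sequence. With 1 library left out, the share difference in percentage points was −1.07 to 1.79 for short contigs, −0.863 to 0.726 for scaffold 1, −0.306 to 0.729 for scaffold 2 and −1.02 to −0.384 for the 31-kb sequence, and the width difference was −0.167 to 2.33 bp. Counting each position once gave −0.0651 for short contigs and −0.130 for scaffold 2, and joining within 50 bp gave a width difference of 5 bp. Alternatives planned for genes (windows, list tests, sirtuin genes) and the upstream window of tag shares were not run. With these counts and this spread, 16.9% of simulated 1.5-fold changes were recovered.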

Other observations

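Of the tests in this part, those on leading clusters 2 kb or more apart and on opposite strands, on the runs of lower clusters and on the nearly silent start site were chosen after the result was seen. Changes of start sites that face away from each other were weakly correlated. Among 237 pairs of leading clusters on opposite strands, oriented outward and 500 bp or less apart, the log2 differences correlated across pairs (Pearson r = 0.341, permutation p = 1e-05, the smallest 100000 permutations can give; Spearman rho = 0.234, p = 0.0003). Pairs are not independent replicates, and r was 0.362 without the 2 pairs whose minus-strand member lay farthest from the median. The plus-strand members were not used for this choice. The pair at 1281456 and 1281738 of scaffold 1 (log2 −2.48 and −3.65) therefore stayed in. In 17 of the 19 pairs with both members called, the direction was the same, while in 77 pairs only 1 member was called. Control by a shared promoter region is a hypothesis that this correlation (0.341) is consistent with, and a wider domain of change was not tested separately.

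Some start sites were used far more in the disruptant. The plus-strand cluster of scaffold 1 at 1490041 to 1490119 had 3 tags over the control and 82 over the disruptant libraries, which is 3.93% of the disruptant level in the control (95% interval 0.794% to 11.9%). The minus-strand clusters at 1315859 to 1315875 of scaffold 1 and at 1745286 to 1745335 of scaffold 2 had 5 and 11 control tags against 92 and 133 disruptant tags (shares of 5.84%, interval 1.85% to 14.1%, and 8.89%, interval 4.33% to 16.4%). These were chosen by size after their values were seen.

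The grouping of changed clusters may come from several clusters of 1 transcription unit. The tables leave this open for much of the grouping, since leading clusters 2 kb or more apart gave a ratio of 1.20 to shuffled calls (permutation p = 0.102). It cannot account for leading clusters on opposite strands less than 2 kb apart, since a unit lies on 1 strand, and there the ratio was 1.95 (47 pairs against 24.1, permutation p = 0.0001, the smallest possible). For each of the 23 lower runs, the share of control tags that its tested clusters kept together was taken. The lowest was 20.01% (95% interval 19.0% to 21.1%), above the 2.72% of the nearly silent site. The interval of 1 of their 121 clusters, at 66287 to 66312 of scaffold 1 (4.99%, 0.998% to 15.3%), reaches that site's. These shares argue against a loss of the whole stretch from the disruptant genome only where the tags have no other match. Whether that holds is not known, since the treatment of reads with several matches is not given. The nearly silent site is also not a known deletion. Positions outside tested clusters are not covered by these shares. In the gap of the 15.6-kb run on scaffold 1, the minus-strand 100-bp bins from 1065901 and 1068301 had 12, 9 and 10 and 36, 15 and 17 tags in the control libraries against 0, 0 and 0 and 1, 2 and 1 in the disruptant, while the plus-strand bin from 1069201 had 10, 3 and 8 against 4, 5 and 8. The loss of a part of a run therefore stays open. Regional regulation in the disruptant and neighbouring promoters that act on each other stay open, and copy number was not tested for the higher runs.

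The nearly silent start site on scaffold 2 at 1165210 to 1165334 kept 2.72% of its control tags in the disruptant (95% interval 2.19% to 3.35%). A deletion of the site in the disruptant, with the remaining tags crossing over from other libraries, is a candidate explanation. The lowest share at a nearly vanished cluster more than 10 kb away was 3.93% (0.794% to 11.9%), an interval that overlaps, and no measure of such crossing was at hand, so a deletion and a strong repression cannot be told apart. The clusters at 1164459 to 1164637 on the minus strand (906 against 828 tags) and at 1167824 to 1167980 on the plus strand (2230 against 1900) kept most of their tags. The plus-strand cluster at 1162656 to 1162726, beyond the first of these, fell 4.49-fold. It lies outside the site, and whether a deletion of the site would lower it too was not tested. Whether the site belongs to the disrupted gene was not tested, since no gene annotation was used.

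The count of changed clusters was 999 with the strains as labelled, the 1 split of 10 with a count that large, and 0 was the highest count of the other splits of the 6 libraries into 3 and 3. For start-site usage the labelled split gave 23 clusters and the highest other split 1. With 10 splits the share cannot fall below 0.05. Each other split puts libraries of both strains in each group, so a strain difference adds to the spread within its groups. The counts of those splits therefore do not show what libraries without a strain difference would give.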
